A study of Tursiops truncatus with 17 samples.

How the data were processed

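RNA was extracted from about 100 mg of frozen cerebral cortex per dolphin with a lipid tissue column kit, and messenger RNA libraries were made from 600 ng of total RNA with 14 cycles of PCR, per the labels. The labels give a median RNA integrity number of 9.1 (interval 8.9 to 9.5) over the 17 samples. The submitters' processing notes name Trim Galore 0.6.1 and STAR 2.5.2a; the counting tool, genome build and annotation are not given in the sources used here. The deposited signal is 1 normalised value per gene and library. Each nonzero value was a whole multiple of the value of 1 read in its library: 100% of them came out whole within 0.01 (largest deviation 0.000239), and the divisors equalled factors recomputed here by the trimmed mean of M values (TMM). The deposited values are therefore CPM, with each library's size scaled by TMM. The recovered reads gave the depth, and a value of 3 reads, the floor used for counting error, was 0.158 to 1.71 depending on the library. Exact binomial intervals (95%) and floors cover counting error only, since reads were copied by PCR.

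Of the 21265 genes in the files 3723 had no reads. Genes were kept by edgeR's filterByExpr by group (minimum count 10, minimum total 15, TMM sizes), which left 13548. The main test was limma-trend on log2(value + 1) with season as the only term, and Benjamini-Hochberg adjusted p under 0.05 counted as passing; log2 changes and their SE are on that scale. The groups were taken from the treatment label, all 17 libraries entered the fit, and source names give each library its own dolphin. The plan had assumed counts and named edgeR's quasi-likelihood test; because the values are normalised, limma-trend was used, as the plan provided for that case, and edgeR on the recovered reads became an added alternative. The filter on low values for normalised data had not been fixed in the plan and was settled after the data were seen.

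The 40 lists of genes and cell type markers, the rule for named genes, the tests and the settings listed first below were fixed before the data were examined. Named genes are the 12 higher and 12 lower with the smallest p among those that passed, had a symbol and had a mean of at least 1; up to 4 members of each list with the smallest p; and GAD1, GAD2, APP, APOE, MAPT, TARDBP, GFAP, CIRBP and RBM3. A few genes that this rule names are not reported here, and they stay in every fit, count and list. Other list members that passed are named where a count of 5 or fewer, or a list's passing members, are spelled out, chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, whose p tests whether a list's genes move, on balance, one way and does not compare the list with other genes. The list score is the mean log2 level of a list's tested members in a dolphin, tested by a two-sided exact permutation test over 24310 splits and adjusted over 40 lists. In fits with a covariate, season was permuted while the covariate stayed in place. These p-values can be too small where season and covariate go together. camera called 16 lists, 7 higher and 9 lower, and 0 of these calls held with an estimated correlation; fry called 8 lists and the list scores 8.

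The settings tried were relative log expression and upper-quartile scaling, DESeq2 on the recovered reads, limma-voom with quality weights, robust variance, no filter, a filter of 1 in 8 libraries, a pseudocount of 0.1, other thresholds, 3 surrogate variables, the oligodendrocyte marker level as a covariate, and leaving out each library. Added after the data were seen were edgeR, the ratio of mitochondrial to other reads or the pan-neuronal marker level as a covariate, and leaving out bloom 5 and 9 or bloom 5, 6 and 9. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and sva 3.50.0. The test was run on simulated data for this comparison with 13673 genes and 200 changed genes: it recovered 58.2% of 98 genes with a log2 change of 1 and 93.9% of 98 with a log2 change of 2, with 7 false calls among 156, and it called 0 genes by either tool and 0 lists with no change simulated. Simulated genes were drawn independently of each other, so the 0 lists do not show how camera behaves when genes of a list vary together. Apart from the changed genes, all simulated libraries had the same mean profile, and none stood apart as bloom 5, 6 and 9 did. The shares recovered and the false calls may therefore differ in the real data.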

Results

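Messenger RNA of the cerebral cortex was sequenced from 17 bottlenose dolphins (Tursiops truncatus), of which 8 were sampled in a non-bloom season and 9 in a bloom season. Bloom here is the submitters' word for the season of collection, and the title of the series places the animals in an estuary. The tissue was frozen archived necropsy material, with 1 library from each dolphin, and dolphins are numbered here within their group in the order of deposition. The labels give no sex, age, date, body temperature or sequencing batch, so no within-batch values are given and a batch that followed the season cannot be told apart from it. The comparison asks which transcripts of the cortex differed between the seasons. No library matched another within sampling noise; the closest pair, bloom 3 and bloom 7, had a chi-square of 13.8 per gene.

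The recovered totals ran from 7680050 to 15635292 reads per library. Non-bloom libraries held 13992634 ± 1193481 reads (SD, n = 8) and bloom libraries 11079035 ± 1668681 (SD, n = 9), so the mean decreased by 2913599 (exact permutation test over 24310 splits, two-sided, p = 0.000288, adjusted p = 0.00115 over 4 library measures). Transcripts of the mitochondrial genome took between 9.68% and 22.1% of the reads in the non-bloom libraries. In the bloom libraries they took between 1.47% (95% exact binomial interval 1.46% to 1.47%) and 77.2% (77.1% to 77.2%), and the intervals cover counting error only. Bloom 9, bloom 5 and bloom 6 had the highest mitochondrial shares, 77.2%, 57.0% and 33.5%, which left 1753799, 4040260 and 6719850 reads for all other genes, the fewest of the 17 libraries. The group difference in mitochondrial share was 12.5 percentage points (exact permutation p = 0.235). The first principal component held 48.9% of the variance and placed bloom 5, bloom 6 and bloom 9 at 106, 88.8 and 80.4, while the other 14 libraries lay between -50.8 and 21.1.

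**Figure D1:**
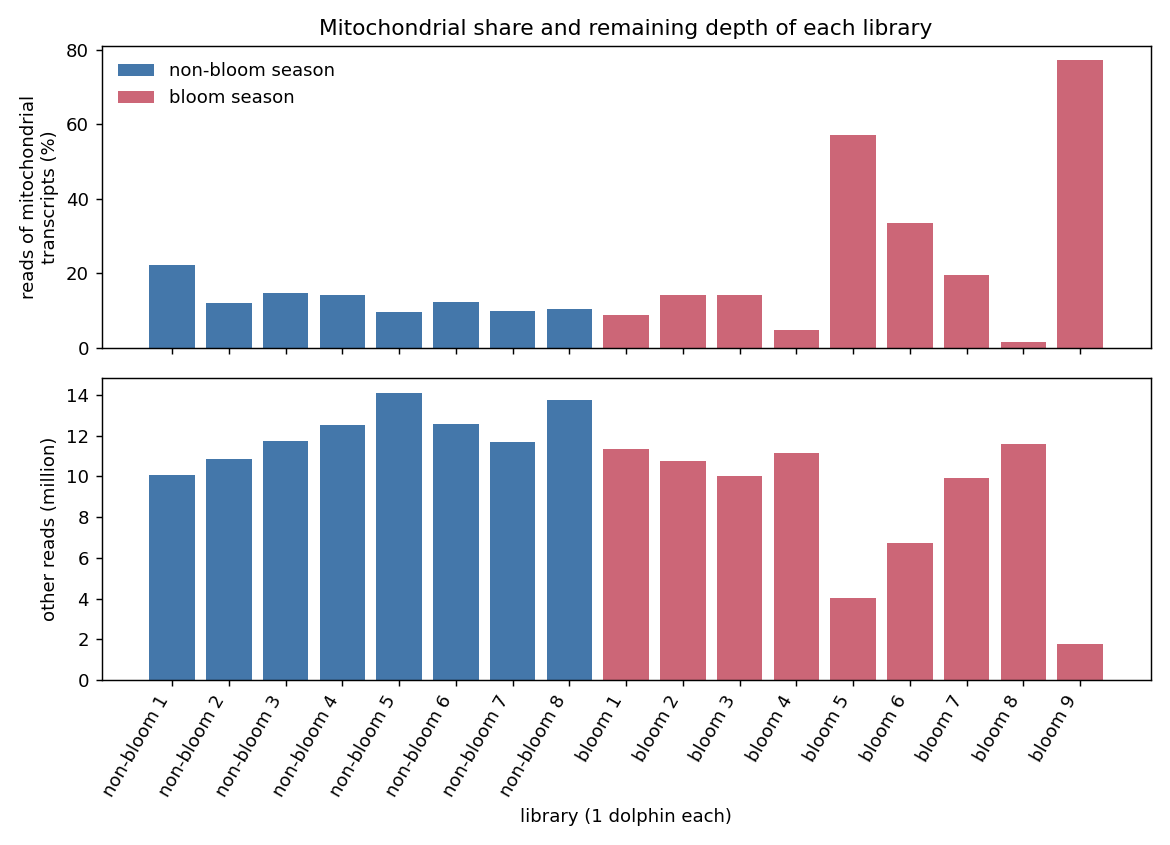
Share of reads from mitochondrial transcripts (top, percent) and reads from all other genes (bottom) in each of the 17 libraries, 1 bar per dolphin. Bloom 9, bloom 5 and bloom 6 have mitochondrial shares of 77.2%, 57.0% and 33.5% and the fewest other reads, 1753799, 4040260 and 6719850.

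**Figure D2:**
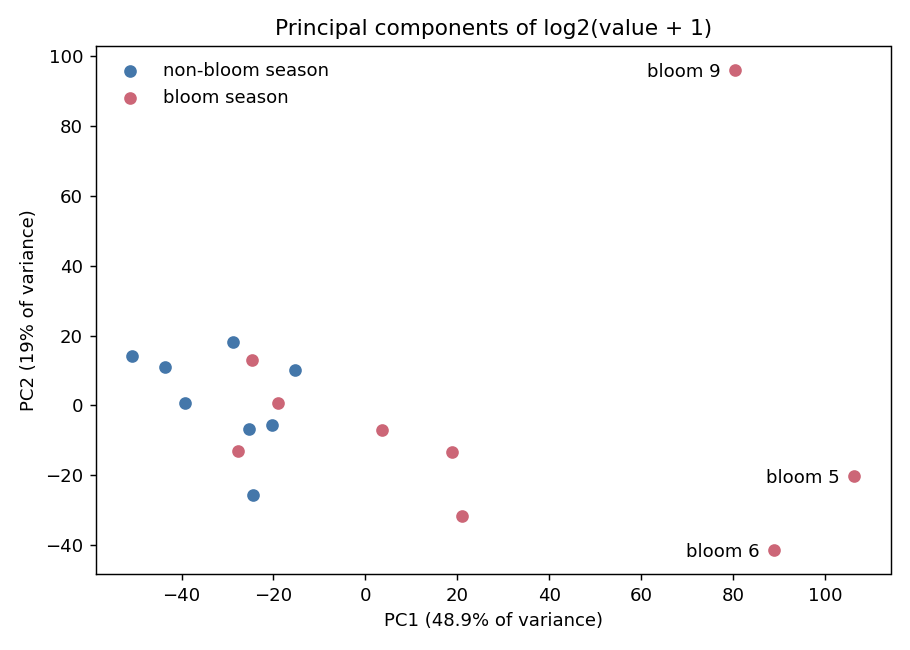
First and second principal components of log2(value + 1), 1 point per library, coloured by season. Bloom 5, bloom 6 and bloom 9 lie above 80 on the first component, which holds 48.9% of the variance.

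In the bloom-season cortex ACAP1, which encodes an Arf GTPase-activating protein, rose from 4.91 ± 0.601 in non-bloom dolphins (SD, n = 8) to 11.4 ± 2.28 (SD, n = 9), a log2 change of 1.06 (SE 0.13, adjusted p = 0.00217). KIF7, a kinesin of the primary cilium that acts in Hedgehog signalling, rose from 2.07 ± 0.356 to 5.22 ± 0.953, and the zinc finger gene ZNF235 rose from 14.5 ± 0.779 to 25.3 ± 2.99. RBM39, a splicing factor, rose from 105 ± 6.16 to 153 ± 10.7, with a log2 change of 0.54 (SE 0.09, adjusted p = 0.00680). Among the genes that fell, the cold-inducible RNA-binding protein RBM3 went from 177 ± 38.5 to 79.0 ± 34.3 and the GABA-synthesizing enzyme GAD2 from 61.3 ± 31.0 to 13.0 ± 10.2. All values are the deposited normalised values, and log2 changes are on the log2(value + 1) scale, which understates the change of low genes.

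Of 13548 genes tested, 1241 changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 606 higher and 635 lower in the bloom season. edgeR on the recovered reads called 1123 genes, and its split was 826 higher and 297 lower, or 73.6% higher against 48.8% in the limma fit. Both tests called 864 genes in the same direction, 575 higher and 289 lower. The median log2 change over all genes tested was -0.0034. The number of genes rested on individual libraries. It was 267, 61, 551, 564, 93, 209 and 66 without non-bloom 1, 2, 3, 5, 6, 7 and 8. It was 2895, 227, 2316, 287, 160, 205 and 2690 without bloom 1, 2, 4, 5, 6, 7 and 8. Without bloom 5, 6 and 9 together it was 320, of which 256 were among the 1241, and all 1238 of the 1241 genes that could still be tested kept their direction. The 1241 genes were chosen by p with all libraries, which by itself favours a kept direction. With the mean level of the pan-neuronal markers as a covariate 4 genes passed, all higher, and 3 of them were among the 1241. Of the 174 genes named by the rule fixed for this purpose and reported here 70 passed, 16 of these passed whichever library was left out, and ACAP1, KIF7 and ZNF235 passed in all settings tried. The rule takes genes with the smallest p in this same fit, so these shares do not describe the other genes. Of all 1241 calls, 61 were kept without non-bloom 2.

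The other 8 genes with the smallest p among those higher were ARHGEF19, COL9A1, STAC3, ANKZF1, FAM193B, BCAT2, SIX5 and PAOX. COL9A1, a chain of type IX collagen, rose from 31.8 ± 5.82 to 58.9 ± 9.80. BCAT2, the mitochondrial branched-chain aminotransferase, rose from 11.7 ± 2.05 to 24.9 ± 7.00, and PAOX, a polyamine oxidase, from 13.7 ± 2.66 to 32.4 ± 11.0. Among these 12 genes the log2 change ran from 0.54 for RBM39 to 1.89 for SIX5 (SE 0.31), and every bloom library lay above the non-bloom median in each of them. Picking genes by smallest p in this fit favours such a separation. ACAP1 lies on GeneScaffold_2224 from 216594 to 227325, as given in the files, whose genome build is not given in the sources used here.

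Among the 12 lower genes with the smallest p, the largest log2 change was that of S100A12, a calcium-binding protein of neutrophils, at -2.87 (SE 0.57, adjusted p = 0.0178). Its values went from 29.2 ± 36.4 to 2.27 ± 2.65. ETNK1, an ethanolamine kinase, fell from 15.8 ± 3.35 to 7.88 ± 2.99. CHAF1A, a subunit of chromatin assembly factor 1, fell from 39.1 ± 5.22 to 23.9 ± 5.57, and SUPT16H, a subunit of the histone chaperone FACT, from 150 ± 15.4 to 101 ± 19.5. RAB3C, a GTPase of synaptic vesicles, fell from 21.2 ± 7.64 to 5.83 ± 4.49. FGFBP3, DHX36, CLGN, MINAR1, SLC35E3 and RBM3 were also in this group, and every bloom library lay below the non-bloom median in all 12. These too were picked by smallest p, which favours such a separation.

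GABA signalling and interneuron transcripts fell in the bloom season. GAD1, the other GABA-synthesizing enzyme, went from 154 ± 86.0 (SD, n = 8) to 35.2 ± 30.5 (SD, n = 9), a log2 change of -2.51 (SE 0.59, adjusted p = 0.0296). GAD2 changed by -2.39 (SE 0.52, adjusted p = 0.0238). SLC32A1, the vesicular GABA transporter, fell from 42.5 ± 16.2 to 14.1 ± 10.4, and LHX6, a transcription factor of interneurons from the medial ganglionic eminence, from 6.58 ± 2.77 to 2.64 ± 2.11. Of 21 genes of GABA synthesis, release and receptors, 7 fell (GAD2, GAD1, GABRG3, SLC32A1, GABRB2, GABRA4 and GABBR1) and 0 rose; 16 fell when adjusted over the list alone. Of 16 interneuron markers, 6 fell (GAD2, GAD1, SLC32A1, LHX6, KIT and DLX1), and 11 when adjusted over the list alone; 3 of these 6 are in both lists. edgeR called 4 of each list, GAD2, GAD1 and SLC32A1 in both, GABRG3 and LHX6. The mean log2 level of the interneuron markers per dolphin differed by -1.09 (exact permutation test, adjusted p = 0.0161 over 40 lists) and that of the GABA list by -0.999 (exact permutation, adjusted p = 0.0161). camera gave adjusted p = 6.49e-05 and 1.68e-05 for these lists, and adjusted p = 0.588 with an estimated correlation for each. The call of GAD1 was lost without non-bloom 1, 2, 6, 7 or 8 or bloom 7, where its adjusted p was at most 0.0672, and without bloom 5 and 9 or bloom 5, 6 and 9 together. That of GAD2 was lost without non-bloom 2, 6 or 8, and without bloom 5, 6 and 9 together. Both were lost with the pan-neuronal covariate, where the log2 changes were -1.39 (SE 0.48) for GAD1 and -1.56 (SE 0.48) for GAD2; without bloom 5, 6 and 9 they were -1.62 (SE 0.43) and -1.75 (SE 0.46).

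**Figure D3:**
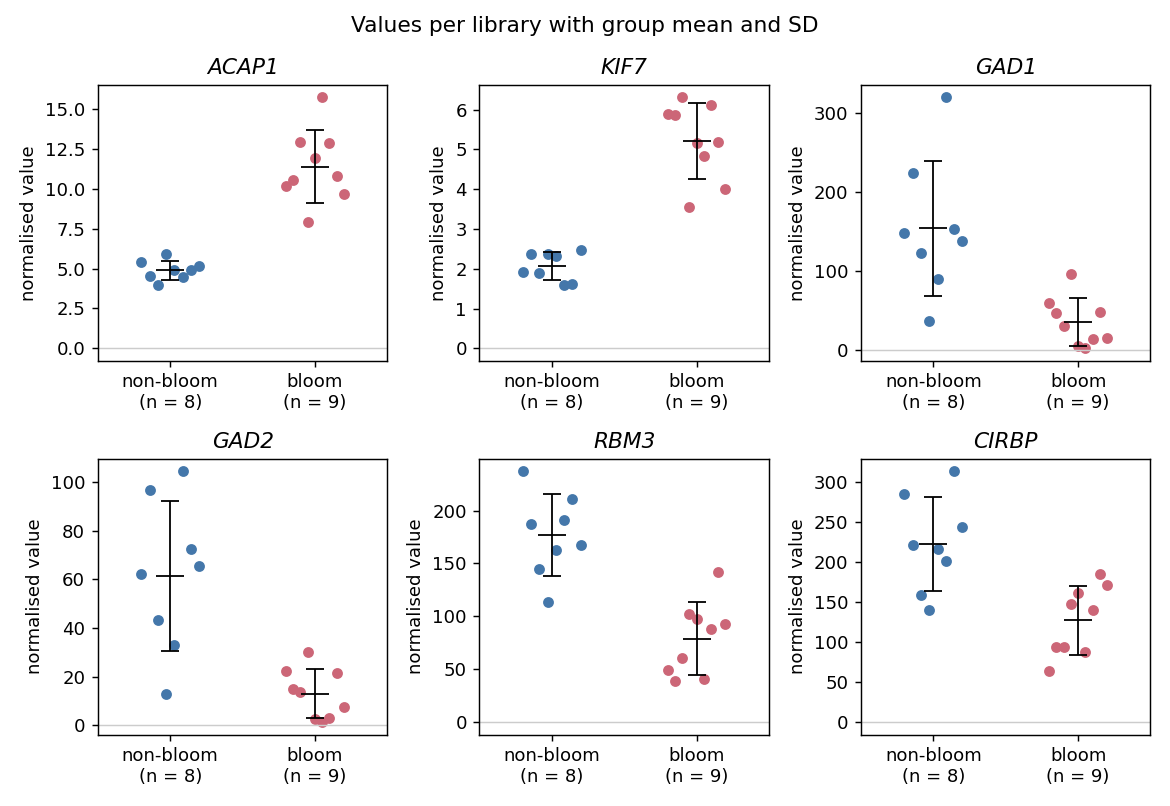
Normalised values of 6 genes in each library, with the group mean and SD as horizontal line and bar, for 8 non-bloom and 9 bloom dolphins. ACAP1 and KIF7 do not overlap between the groups, and all bloom libraries lie below the non-bloom median for GAD1, GAD2, RBM3 and CIRBP. Of all 13548 genes tested, 89 do not overlap between the groups.

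Transcripts of synaptic vesicle release were lower as a group. SYT1, the calcium sensor of vesicle fusion, fell from 902 ± 149 to 396 ± 235 (log2 change -1.52, SE 0.40, adjusted p = 0.0365). RIMS1 and NSF also fell, by -0.86 and -1.66 on the log2 scale. Of the 20 tested members 4 passed, 17 when adjusted over the list alone, and all 20 had negative changes; edgeR called 1, SYT1. The list score differed by -1.15 (exact permutation, adjusted p = 0.0189), and camera gave adjusted p = 7.14e-07, or adjusted p = 0.588 with an estimated correlation. Among 26 genes of glutamate receptors and transporters GRIN3A, GRIA1 and GRIN2B fell, 18 fell and 1 rose when adjusted over the list alone, and the score differed by -0.69 (exact permutation, adjusted p = 0.0275; camera adjusted p = 0.000488, and adjusted p = 0.588 with an estimated correlation). Of 13 neuropeptide genes, TAC1, which encodes substance P, fell from 30.5 ± 12.3 to 13.1 ± 9.53, and 7 fell when adjusted over the list alone. edgeR called GRIN3A and GRIN2B but not GRIA1, and 0 neuropeptide genes. With 1 library left out the call was lost in 10, 12 and 14 of 17 fits for SYT1, RIMS1 and NSF, in 9, 11 and 11 for GRIN3A, GRIA1 and GRIN2B, and in 13 for TAC1. The neuropeptide score differed by -0.72 (exact permutation, adjusted p = 0.0389; camera adjusted p = 0.00574, and adjusted p = 0.588 with an estimated correlation). Without bloom 5, 6 and 9 the adjusted p of the scores was 0.0599 for the GABA list, the interneuron markers and vesicle release, 0.120 for the glutamate list and 0.211 for neuropeptides (exact permutation). The scores differed there by -0.52, -0.62, -0.52, -0.26 and -0.46 in that order. Over 27 other settings the highest adjusted p of these 5 scores was 0.124, 0.124, 0.247, 0.406 and 0.227 (permutation), each with the pan-neuronal covariate. With that covariate they differed by -0.52, -0.53, -0.30, -0.24 and -0.42. SYT1 and SNAP25 are both vesicle release genes and pan-neuronal markers, so a part of the smaller vesicle release difference is built in.

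Markers of all neurons and of excitatory neurons had lower group values, with few single genes past the threshold. Of 12 excitatory markers 1 fell by limma, over all genes and adjusted over the list alone, and 0 by edgeR (5 lower at an unadjusted p under 0.05 by limma). SYT1 was the only one of 12 pan-neuronal markers to pass, over all genes and adjusted over the list alone, while MAP2 changed by -1.38 (SE 0.48, adjusted p = 0.0650) and SNAP25 by -0.67 (SE 0.27, adjusted p = 0.0907). The scores differed by -0.63 for excitatory markers (exact permutation, adjusted p = 0.0762) and -0.63 for pan-neuronal markers (exact permutation, adjusted p = 0.0581). They differed by -0.17 and -0.26 without bloom 5, 6 and 9 (exact permutation, adjusted p = 0.320 and 0.263). camera called both lists lower, with adjusted p = 0.00788 and 0.0127, and adjusted p = 0.588 and 0.612 with an estimated correlation.

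Markers of astrocytes, oligodendrocytes and vessels had higher group values. Of 16 oligodendrocyte markers ERMN rose from 47.5 ± 29.2 to 111 ± 24.6 and MOG, a myelin glycoprotein, from 75.5 ± 30.5 to 120 ± 29.5; 5 rose when adjusted over the list alone, and edgeR called ERMN but not MOG. None of 13 astrocyte markers passed over all genes by limma, 7 were higher at an unadjusted p under 0.05, 6 rose when adjusted over the list alone, and edgeR called FGFR3, ALDH1L1 and ACSBG1 higher; GFAP was at 699 ± 381 and 1940 ± 2077 (log2 change 0.92, SE 0.58, adjusted p = 0.256). SLCO1A2, an organic anion transporter of brain endothelium, and KCNJ8, a pericyte potassium channel, rose by 1.48 and 0.91 on the log2 scale, as 1 of 15 endothelial markers, 0 when adjusted over the list alone, and 1 of 13 markers of pericytes and smooth muscle, 1 when adjusted over the list alone. The laminin genes LAMA3, LAMB2 and LAMA1 rose by 0.76, 1.18 and 1.55 among 21 genes of basement membrane and vascular matrix, of which 4 rose when adjusted over the list alone. edgeR called SLCO1A2, KCNJ8 and the 3 laminin genes higher, and KDR and HSPG2 besides. The calls of ERMN, MOG, SLCO1A2, KCNJ8, LAMA3, LAMB2 and LAMA1 were lost in 3, 12, 13, 9, 2, 9 and 8 of the 17 fits with 1 library left out. camera called the lists of astrocytes, oligodendrocytes, endothelial cells, pericytes and basement membrane higher, with adjusted p = 0.000844, 0.00258, 0.0263, 0.00697 and 0.000180. With an estimated correlation these became adjusted p = 0.588, 0.588, 0.757, 0.588 and 0.588. The list scores of the same 5 groups differed by 1.08, 0.55, 0.60, 0.66 and 0.67 and did not pass (exact permutation, adjusted p = 0.1004, 0.1004, 0.348, 0.1004 and 0.0762). With the pan-neuronal covariate they differed by 0.22, 0.73, -0.16, 0.28 and 0.22, and without bloom 5, 6 and 9 by 0.60, 0.71, 0.41, 0.56 and 0.53.

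All 66 cytosolic ribosomal protein genes tested had positive changes, with a median of 0.70 on the log2 scale, and none passed over all genes or when adjusted over the list alone (limma). At an unadjusted p under 0.05 there were 49, all higher, and edgeR called 2 of them higher, among them RPS3. Nuclear genes of oxidative phosphorylation had a median of 0.25 over 60 genes, and none passed either way by limma; 11 were higher and 3 lower at an unadjusted p under 0.05, and edgeR called NDUFA3 higher. camera called both lists higher, with adjusted p = 3.36e-12 and 0.0106, and adjusted p = 0.588 and 0.856 with an estimated correlation. The scores differed by 0.69 and 0.23 (exact permutation, adjusted p = 0.1004 and 0.287). They differed by 0.18 and 0.025 without bloom 5, 6 and 9, and by 0.33 and 0.17 with the pan-neuronal covariate. Ribosomal protein genes have many near-identical pseudogene copies, so their values may depend on how the authors' counting treated shared reads, which was not tested.

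The cold-inducible RNA-binding proteins fell as a list. RBM3 changed by -1.25 (SE 0.24, adjusted p = 0.0151) and CIRBP, which went from 223 ± 58.5 to 127 ± 43.1, by -0.84 (SE 0.22, adjusted p = 0.0344). SRSF5, a splicing factor and the other member of the list, changed by -0.39 (SE 0.14, adjusted p = 0.0639), and all 3 fell when adjusted over the list alone. The score differed by -0.83 (exact permutation, adjusted p = 0.0132), and camera gave adjusted p = 0.00697, or adjusted p = 0.588 with an estimated correlation. The call of CIRBP was lost without non-bloom 1, 2, 6, 7 or 8 or bloom 2, 6 or 7, where its adjusted p was at most 0.0708, and with the oligodendrocyte covariate or by edgeR without bloom 5, 6 and 9. That of RBM3 was kept whichever library was left out, and both were lost with the pan-neuronal covariate. The log2 changes there were about as large, -1.18 (SE 0.28) for RBM3 and -0.91 (SE 0.25) for CIRBP. The score difference there was -0.80 (SE 0.21, permutation, adjusted p = 0.00740). That p can be too small, because permuting season breaks its link to the covariate (correlation -0.513).

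Genes tied to neurodegenerative disease in people moved in both directions, as did genes at large. Of all 13548 genes tested 1241 passed, 606 higher and 635 lower, and an excess on these lists was not tested. APP, the amyloid precursor, was at 2212 ± 277 in non-bloom and 1490.6 ± 445 in bloom dolphins (log2 change -0.62, SE 0.20, adjusted p = 0.0522), and APOE, the main lipid carrier of the brain, at 1217 ± 553 and 3674 ± 2650 (log2 change 1.39, SE 0.47, adjusted p = 0.0605; 0.0411 by edgeR, and 0.00523 to 0.615 over the 33 other settings). MAPT, which encodes tau, changed by -0.35 (SE 0.19, adjusted p = 0.195), and TARDBP, which encodes TDP-43, by 0.38 (SE 0.14, adjusted p = 0.0751). Of 34 genes on the Alzheimer disease list ZCWPW1 and FERMT2 rose and GSK3B and MEF2C fell; adjusted over the list alone, 4 rose and 5 fell. Of 21 genes on the amyotrophic lateral sclerosis list MATR3 fell, and of 15 on the Parkinson disease list the synaptic vesicle recycling genes SYNJ1 and DNAJC6 fell. Adjusted over the list alone, 2 rose and 5 fell of the former and 2 fell of the latter. edgeR called none of MATR3, SYNJ1 and DNAJC6, and its only call on the amyotrophic lateral sclerosis and Parkinson disease lists was CHCHD10, higher; on the Alzheimer disease list it called the same 4 genes, ADAM17 and APOE higher and SPI1 lower. The calls of MATR3, SYNJ1 and DNAJC6 were lost in 14, 13 and 13 of the 17 fits with 1 library left out, and those of ZCWPW1, FERMT2, GSK3B and MEF2C in 5, 9, 9 and 9. camera called none of these lists, with adjusted p = 0.859, 0.223 and 0.0653. The Alzheimer disease list had a median log2 change of 0.02, while its mean was -0.02 and its test pointed lower.

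**Figure D4:**
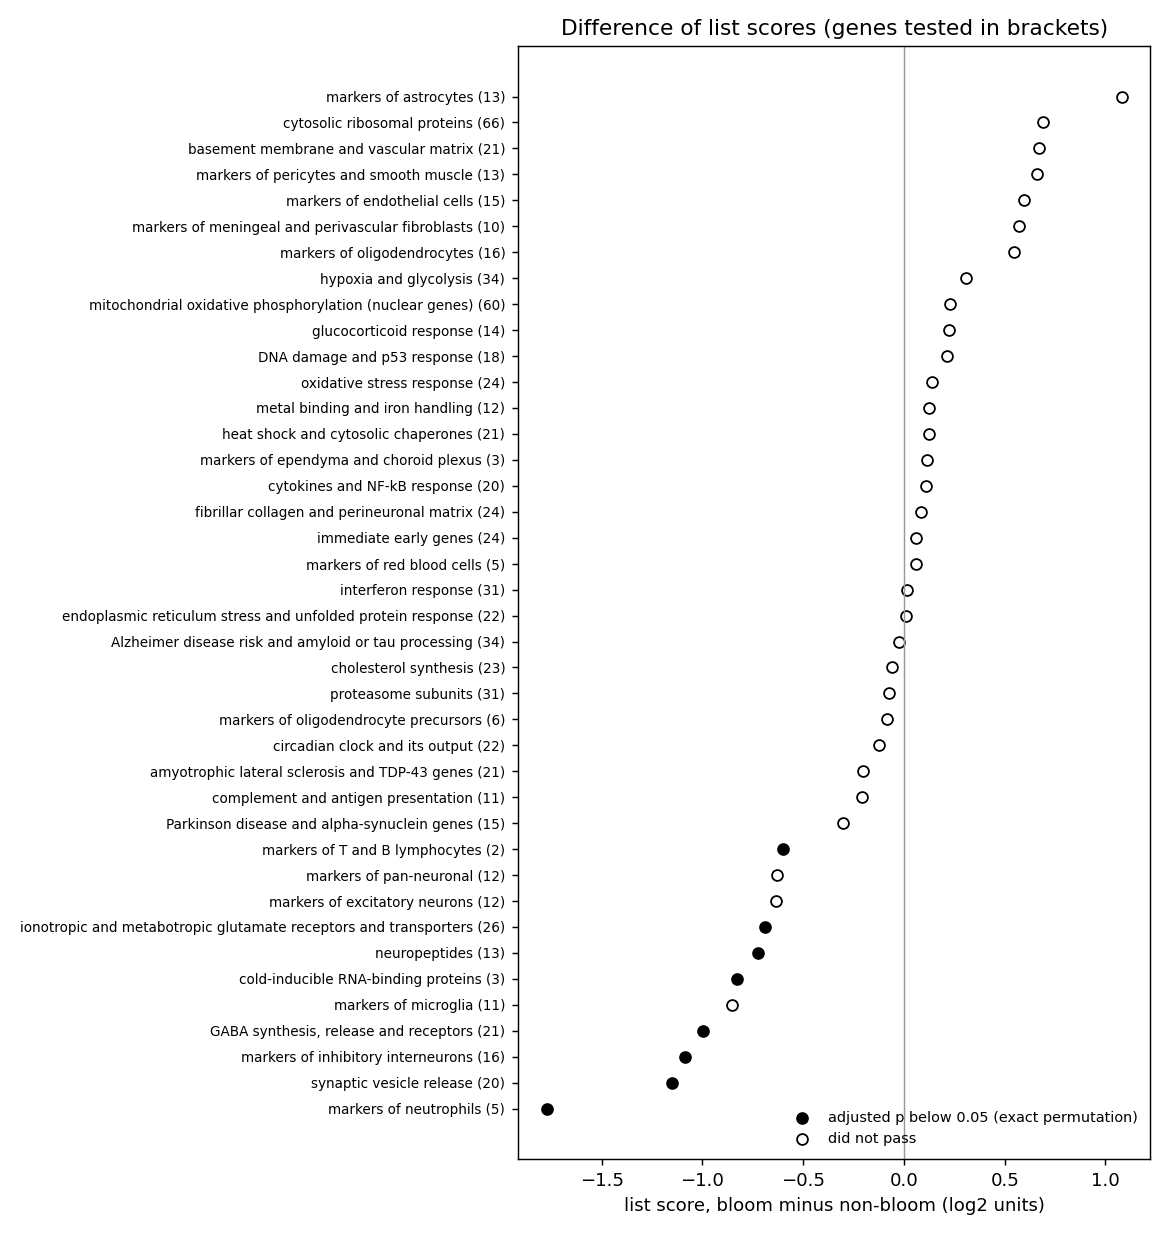
Difference of the mean log2 level of each of 40 gene lists between 9 bloom and 8 non-bloom dolphins, in log2 units, with the number of genes tested in brackets. Filled points mark the 8 lists past an adjusted p of 0.05 in the exact permutation test, all of them lower in the bloom season.

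Stress and immediate early genes showed few changes. CRYAB, a small heat shock protein abundant in oligodendrocytes and astrocytes, rose from 167 ± 64.8 to 529 ± 336, and DNAJB1 from 54.4 ± 7.61 to 80.0 ± 21.3, among 21 heat shock genes. MANF and CRELD2, both secreted on endoplasmic reticulum stress, rose by 0.63 and 0.71 among 22 genes of that response. CDKN1A, the p21 cell cycle inhibitor, and BAX rose by 0.97 and 0.48 among 18 p53 response genes. NDRG1 rose by 1.10 among 34 genes of hypoxia and glycolysis, SRXN1 fell by 0.67 among 24 oxidative stress genes, and none of 24 immediate early genes passed by limma (2 higher and 5 lower at an unadjusted p under 0.05; edgeR called JUN higher). Adjusted over the list alone, 4 heat shock genes rose and 1 fell, 2 endoplasmic reticulum stress genes, 2 p53 response genes and 1 hypoxia gene rose, and 0 oxidative stress or immediate early genes passed. edgeR called each of the genes named as changed here except SRXN1, and HSPB8, DDIT4 and P4HA1 higher besides. Calls were lost in 3 of the 17 fits with 1 library left out for CRYAB, 8 for MANF and NDRG1, 10 for CDKN1A, 11 for CRELD2, 13 for DNAJB1 and SRXN1 and 14 for BAX. camera called none of these 6 lists, with adjusted p from 0.0806 for the p53 response to 0.867. fry called the p53 response higher (adjusted p = 0.0466), with 15 of its 18 genes positive, while its score, which differed by 0.21, did not pass (exact permutation, adjusted p = 0.0570).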

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

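The tests of random splits were planned; the tests on the 3 libraries and on neuron markers in this part were chosen only after the result was seen. 1241 genes changed between the seasons, and chance alone is unlikely to give that count: 1 of 100 splits of the 17 libraries gave as many, the real one, and the highest other count was 0. That is the smallest share this test could give. The same splits gave the same result for the 606 higher genes (1 split, highest other 0) and the 635 lower genes (1 split, highest other 0), which are no separate tests. Chance cannot be excluded for the number of lists called by camera, 16, since 26 of 100 splits gave as many, and the highest other split gave 25. Leaving out bloom 5, 6 and 9 left a median of 0.667 of the log2 change of the 1241 genes (quartiles 0.569 to 0.791, SE 0.8002 times as large). The pan-neuronal covariate left 0.628 (quartiles 0.4934 to 0.770, SE 0.976 times as large), so most changes were smaller in both settings. The 1241 genes were chosen by p in the main fit, which by itself favours smaller changes in other fits. Other sets of 3 bloom libraries were not left out for comparison. Not all lost calls had smaller changes: CIRBP lost its call with the covariate at -0.91 (SE 0.25) against -0.84 (SE 0.22). A part from these libraries or from a lower share of neurons may remain, neither value decides, and the pan-neuronal level itself goes with season (correlation -0.513), while a seasonal difference stays open as untested.

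Interneuron markers were lower in the bloom season, by -1.09 in the list score (SE 0.31, exact permutation, adjusted p = 0.0161). It was assumed, and not tested, that a lower share of all neurons would lower interneuron and excitatory markers alike. The interneuron score fell more, by -0.45 beyond the excitatory score (exact permutation p = 0.0128, not adjusted over lists). With 1 library left out this p was 0.00236 to 0.0254, and without bloom 5, 6 and 9 the difference was -0.44 (exact permutation p = 0.0320). Only under that assumption is a lower share of all neurons not the whole cause. With the pan-neuronal covariate the interneuron score differed by -0.53 (SE 0.23, adjusted p = 0.124), and the call ended because the difference was smaller, so a part from a lower share of neurons may remain. Without bloom 5, 6 and 9 it differed by -0.62 (SE 0.20, exact permutation, adjusted p = 0.0599), and the call ended with a smaller difference there too, so a part from these libraries stays open. A difference in the layer or region dissected, or a loss of interneuron transcripts with season, may account for it; neither was tested.

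RBM3 and CIRBP, whose transcripts rise on mild cooling in mammalian cells, were lower in the bloom season, with a list score difference of -0.83 (SE 0.17). With the pan-neuronal covariate it was -0.80 (SE 0.21, permutation, adjusted p = 0.00740), so the neuronal marker level accounted for little of it in this fit. That p can be too small because season goes with the covariate, so it does not decide whether a lower share of neurons contributes. The call of RBM3 itself ended there (limma adjusted p = 0.127), with a change of -1.18 (SE 0.28) against -1.25 (SE 0.24), about as large with a larger SE. Without bloom 5, 6 and 9 the list score difference was -0.82 (SE 0.20, exact permutation, adjusted p = 0.0200). A candidate explanation is a difference in body or water temperature between the seasons, which the labels do not give, and the interval from death to freezing stays open in the same way; neither was tested.

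Among 444 groups of values checked, 26 had 1 library far from the rest of its group, and chance flags about 1 in 20 groups. The mitochondrial share of non-bloom 1 was 22.1%, with the next at 14.7%. The proteasome score of bloom 9 was 7.27, with the next at 6.90. In bloom 9 the value of FAM193B was 107 (next 49.4), that of TFRC 1.71 (next 19.3) and that of IL4R 1.71 (next 4.18), the last 2 at the floor of 3 reads. In non-bloom 4 STAC3 was at 1.43 (next 0.369), BCAT2 at 16.3 (next 12.8), DHX36 at 44.0 (next 59.0) and EGR1 at 152 (next 84.7). In non-bloom 3 MAPT was at 190 (next 251) and GPX3 at 101 (next 139). In non-bloom 5 TRH was at 4.27 (next 9.45) and NDRG1 at 150 (next 88.4). In non-bloom 7 SLC40A1 was at 15.7 (next 8.11), NDUFV1 at 83.4 (next 148) and HIF3A at 11.1 (next 3.43). In non-bloom 6 MAOA was at 6.30 (next 16.2) and SLC17A6 at 84.1 (next 43.7). ATF3 was at 3.91 in non-bloom 8 (next 1.17) and SRSF5 at 446 in non-bloom 1 (next 282). In bloom 5 TUBA4A was at 145 (next 282) and MOG at 64.9 (next 103). CD59 was at 81.8 in bloom 6 (next 56.3) and ERMN at 55.7 in bloom 8 (next 93.9). In bloom 2 SPI1 was at 1.65 (next 0.660) and ITGAM at 4.95 (next 1.32).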

How the results depend on the processing

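The alternatives by edgeR, with the mitochondrial ratio or the pan-neuronal markers as covariate, and without bloom 5 and 9 or bloom 5, 6 and 9 were chosen only after the result was seen. The 1241 genes changed, with 606 genes higher in bloom season and 635 genes lower in bloom season, kept their direction wherever they could be tested in each setting. They were chosen by p in the same libraries, so a kept direction is no separate support. The counts of genes changed (higher and lower in brackets) moved. They were 3186 (1977 higher, 1209 lower) by DESeq2, 4123 (2082, 2041) by limma-voom with quality weights, 560 (332, 228) with no filter, 3648 (1630, 2018) at an adjusted p under 0.1, 399 (175, 224) with an absolute log2 change of at least 1, and 4797 (2216, 2581) at an unadjusted p under 0.05. They were 579 (339, 240) with surrogate variables, 2126 (862, 1264) with the oligodendrocyte covariate, 4 (4, 0) with the pan-neuronal covariate and 2518 (1098, 1420) with the mitochondrial ratio. They were 566 (398, 168) without bloom 5 and 9, 320 (230, 90) without bloom 5, 6 and 9, and 188 (155, 33) by edgeR without these 3; edgeR on all libraries gave 297 lower. Stricter or looser thresholds change the counts by construction, and the cause was not tested for the others. Relative log expression scaling (1337), upper-quartile scaling (1220), robust variance (1151), the filter of 1 in 8 libraries (1250) and a pseudocount of 0.1 (927) stayed within 1.5 times.

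Leaving out 1 library gave 61 (without non-bloom 2) to 2895 (without bloom 1) genes changed, 54 to 1317 higher and 7 to 1578 lower, again without these libraries. Genes lower in bloom season numbered 411 without bloom 3. The list scores per dolphin past the threshold, 8 with all libraries, numbered 5 without non-bloom 1, 2, 6 or 8, 15 without non-bloom 7, 13 without bloom 1 and 14 without bloom 4. They numbered 17 with the oligodendrocyte covariate, 2 with the pan-neuronal covariate and 2 without bloom 5, 6 and 9. The counts with a covariate rest on permutation p-values that can be too small. The lists called by camera numbered 15 to 18 with 1 library left out, 0 with an estimated correlation and 8 by fry. A sex-linked covariate was not run, nor were list scores with surrogate variables or robust variance. No paired analysis was possible because each dolphin gave 1 library and the numbers were given in order of deposition. Depth limits bloom 9 most, where 3 reads are a value of 1.71.

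The direction turned for these genes that did not pass, with the cause not tested. MAPT was at 0.021 with the pan-neuronal covariate. ATP13A2 and VCAN were at 0.0024 and 0.023 with surrogate variables, MAOA at -0.030 with the pan-neuronal and SOX10 at -0.024 with the oligodendrocyte covariate. ALAS2 and HBB were at 0.15 and 0.37 by DESeq2 and 0.060 and 0.28 by edgeR. JCHAIN was at 0.0083 with upper-quartile scaling and 0.13 with the oligodendrocyte covariate. With 1 library left out JCHAIN ran from -0.093 to 0.032.

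For lists the direction of the set test turned as follows, given as the median log2 change, with the cause not tested; of these lists the endothelial markers alone had been called, and were at -0.29 with the pan-neuronal covariate. With surrogate variables the medians were -0.044 (immediate early), -0.11 (endoplasmic reticulum stress), 0.017 (oxidative stress), -0.011 (interferon), -0.13 (cytokines), -0.044 (complement), -0.15 (hypoxia), -0.082 (glucocorticoid) and -1.77 (red blood cells). With the pan-neuronal covariate they were -0.11, -0.075, 0.024, -0.22, -0.34, -0.20, -0.12, -0.090 and -1.43 for the same lists, -0.17 for oligodendrocyte precursors and 0.014 for ependyma. Without bloom 5, 6 and 9 they were 0.017 (immediate early), 0.0069 (oxidative stress), -0.19 (interferon), -0.13 (cytokines), -0.11 (complement), 0.013 (hypoxia), -0.12 (oligodendrocyte precursors) and -1.60 (red blood cells). Without bloom 5 and 9 they were -0.016 (Alzheimer disease), -0.12 (interferon) and -0.061 (complement). With no filter they were 0.091 (immediate early), -0.022 (complement), -0.33 (oligodendrocyte precursors) and -0.010 (ependyma). With the oligodendrocyte covariate they were 0.062 (endoplasmic reticulum stress), -0.19 (metal binding) and -0.14 (oligodendrocyte precursors), with the mitochondrial ratio -0.13 (interferon), and with upper-quartile scaling 0.10 (oligodendrocyte precursors). With 1 library left out the medians ran from -0.032 to 0.048 (Alzheimer disease), -0.021 to 0.28 (complement), -0.21 to 0.14 (cytokines), -0.033 to 0.064 (endoplasmic reticulum stress), -0.059 to 0.23 (immediate early), -0.15 to 0.24 (interferon), 0.0019 to 0.34 (ependyma) and -0.063 to 0.23 (oligodendrocyte precursors).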

Other observations

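The tests by edgeR, with the pan-neuronal covariate, without bloom 5 and 9 or bloom 5, 6 and 9, and on the order of genes in the files were chosen only after the result was seen. Transcripts of neutrophils were lower in the bloom season. S100A12 and S100A9, calcium-binding proteins abundant in neutrophils, fell by 2.87 and 2.25 on the log2 scale (limma adjusted p = 0.0178 and 0.0387). Of 13 neutrophil markers listed 8 were in the files and 5 were tested, and all 5 fell when adjusted over the list alone. By edgeR S100A12, S100A9 and CSF3R were called lower. The score differed by -1.77 (SE 0.49, exact permutation, adjusted p = 0.0161), and camera gave adjusted p = 0.00165, or adjusted p = 0.588 with an estimated correlation. Without bloom 5, 6 and 9 the score differed by -1.78 (SE 0.57) and no longer passed (exact permutation, adjusted p = 0.0599). With the pan-neuronal covariate the score differed by -2.05 (SE 0.57, permutation, adjusted p = 0.00740), a p that can be too small because season goes with the covariate. CD3G, a chain of the T cell receptor complex, fell from 6.03 ± 1.21 (SD, n = 8) to 2.65 ± 1.90 (SD, n = 9), as 1 of 2 lymphocyte markers over all genes and adjusted over the list alone, beside JCHAIN with a log2 change of -0.02. These 2 genes were the only ones tested of 15 lymphocyte markers listed, all 15 of them in the files. Their score differed by -0.60 (exact permutation, adjusted p = 0.0161, and camera adjusted p = 0.359). For these markers of T and B lymphocytes the score did not pass with the pan-neuronal markers as covariate (-0.36, permutation, adjusted p = 0.0740). It did not pass with no filter on low values either (-0.077, exact permutation, adjusted p = 0.0980). With bloom libraries 5, 6 and 9 left out it passed, at -0.39 (exact permutation, adjusted p = 0.0200). None of 11 microglia markers passed over all genes or adjusted over the list alone by limma; 4 were lower at an unadjusted p under 0.05, edgeR called CD68, SPI1 and CSF1R lower, and camera gave adjusted p = 0.0512. The call of S100A9 was lost without non-bloom 1, 2, 3, 5, 6, 7 or 8 or bloom 2, 5, 6 or 7, that of CD3G also without non-bloom 4, and that of S100A12 was kept whichever library was left out. All 3 were lost with the pan-neuronal covariate, where the log2 changes of S100A12 and S100A9, -3.03 (SE 0.66) and -2.54 (SE 0.71), were no smaller and that of CD3G was -0.70 (SE 0.33) against -1.18 (SE 0.34). All 3 were also lost by edgeR without bloom 5, 6 and 9, S100A9 and CD3G also by limma without these libraries and with no filter, S100A9 without bloom 5 and 9, and CD3G with a pseudocount of 0.1, with surrogate variables and by edgeR on all libraries.

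SLC6A13 and SLC22A6, transporters of the meninges, rose by 1.67 and 1.39 on the log2 scale among 10 markers of meningeal and perivascular fibroblasts, and 2 rose when adjusted over the list alone (camera adjusted p = 0.0687). BCAN, a proteoglycan of the brain matrix, rose by 1.41 while MMP9, a matrix metalloprotease, and TNR, a glycoprotein of perineuronal nets, fell by 1.85 and 1.47 among 24 genes of fibrillar collagen and perineuronal matrix; 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.619). PDGFRA fell by 1.84 as 1 of 6 markers of oligodendrocyte precursors, 1 also when adjusted over the list alone (camera adjusted p = 0.976, pointing higher, while the score differed by -0.08). SLC25A37, a mitochondrial iron importer, rose by 0.76 as 1 of 5 markers of red blood cells, 1 when adjusted over the list alone; the median of that list was -0.43 while its test pointed higher (camera adjusted p = 0.405). None of 3 markers of ependyma and choroid plexus passed over all genes by limma or edgeR; 1 was higher and 1 lower, both at an unadjusted p under 0.05 and when adjusted over the list alone (camera adjusted p = 0.823). Of the genes named as changed in this paragraph edgeR called all but TNR and PDGFRA. Calls were lost in 2 of the 17 fits with 1 library left out for SLC25A37, 5 for SLC6A13, 10 for SLC22A6, 11 for MMP9 and PDGFRA, 12 for BCAN and 13 for TNR.

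HLF, a transcription factor of the clock output, fell from 52.8 ± 7.06 to 31.0 ± 10.9 as 1 of 22 circadian genes (2 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.296). CDKN1A was the only one of 14 glucocorticoid response genes to pass, over all genes and adjusted over the list alone; the median of that list was -0.0047 while its test pointed higher (camera adjusted p = 0.582). HERC6 rose by 0.63 and CMPK2 fell by 0.67 among 31 interferon response genes, and 1 rose when adjusted over the list alone; the median was -0.04 while the test pointed higher (camera adjusted p = 0.867). None of 20 cytokine and NF-kB genes, 11 genes of complement and antigen presentation, 31 proteasome subunits, 23 cholesterol synthesis genes or 12 genes of metal binding and iron handling passed over all genes or adjusted over the list alone by limma. At an unadjusted p under 0.05 these 5 lists held 2, 1, 0, 2 and 3 higher and 1, 0, 8, 2 and 2 lower genes, and edgeR called 1 gene, MT3, higher. edgeR called HLF, CDKN1A and HERC6 but not CMPK2, and with 1 library left out their calls were lost in 8, 10, 10 and 14 of 17 fits. camera gave them adjusted p = 0.582, 0.874, 0.214, 0.657 and 0.619; the cytokine list had a median of -0.03 and the complement list a score difference of -0.21, while their tests pointed higher.

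The order of genes in the files followed the p-values of edgeR on the recovered reads, with a Spearman correlation of 0.9996 across 13548 genes, against 0.937 for the p-values of limma. Genes are not independent replicates. The first 100 genes of the files, tested or not, shared 93 with the first 100 by edgeR and 75 with the first 100 by limma.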
